A study of Mus musculus with 12 samples.

How the data were processed

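RNA was sequenced from pachytene spermatocytes (PS) and round spermatids (RS) of mice with and without a conditional Hdac3 deletion in germ cells. Total RNA was extracted with TRIzol and sequenced from strand-specific libraries made with a TruSeq Stranded Total RNA kit, per the labels' protocols. How the cells were isolated is not given in the sources used here. The 12 libraries form 4 groups of 3, and the submitters describe them as biological triplicates, so p-values measure the spread between these samples. The control titles give the genotype Hdac3fl/+ and the genotype label reads wild type, and no cre is named for them.

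Gene counts were made by the authors with HISAT2 2.1.0 and HTSeq on the mouse build mm10, per the submitters' processing notes, and were deposited as 2 tables, 1 per cell type, of 21429 gene symbols each. The annotation, the strand setting of the counting and the settings of the authors' own test are not given in the sources used here, so antisense and overlapping genes, and genes with near-identical copies, are uncertain. Each table also holds the authors' log2 fold change of KO against control and p-values, unadjusted and adjusted. The notes also name DESeq2. The 12 columns of normalized values were not used.

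Each group has 3 count columns. In each group 1 column carries no number, and it matches the title of replicate 1 through the sample description. The column with the number 2 matches the description of the sample titled replicate 3. The column with the number 3 matches its group and no single title, so it was used as a replicate without a number and is called the remaining replicate. To check whether replicate numbers pair the samples, deviations of log2 counts scaled to library size (CPM) from group means were correlated across genes. Within a cell type the correlation was 0.310 to 0.408 for libraries with the same number, the remaining replicates taken as a pair, and -0.416 to 0.00420 for libraries with different numbers. Across cell types it was 0.134 to 0.495 for the same number and -0.478 to 0.199 for different numbers, so there the ranges overlapped. All same-number correlations were over 0.1, and the numbers were read as pairing the samples. The pairing of replicates 1 and 3 comes from the labels and that of the remaining replicates from elimination. No 2 replicates of a group agreed within sampling noise: the lowest chi-square per gene was 16.6.

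Total gene counts ranged from 11205732 to 17467583 per library. A count of 3, taken as the floor, was worth 0.172 to 0.268 CPM. Intervals of ratios of low counts are 95% exact counting intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

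The following choices were made before the data were examined: the groups, the tests, the gene lists, the rule for named genes and the alternative settings, except where stated. KO was compared with control in each cell type with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, on the counts as deposited, after TMM scaling and the filterByExpr filter, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each cell type had its own fit of 6 libraries and 4 residual degrees of freedom, or 2 with the replicate block. The interaction of genotype and cell type and the comparison of control RS with control PS came from 1 fit of all 12 libraries. Log2 fold changes are edgeR's, with a standard error from the same fit, and log2 CPM used a prior count of 2. Levels are given as mean ± SD of CPM.

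Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. None of the list calls in PS, RS or the interaction held with the estimated correlation. The 25 lists covered meiotic prophase, the meiotic divisions, pachytene regulators and the piRNA pathway, post-meiotic transcription regulators, transition proteins with protamines and testis linker histones, the acrosome, the flagellum and sperm energy metabolism. They also covered markers of spermatogonia, Sertoli, Leydig, peritubular, macrophage, endothelial and red blood cells. The others were the HDAC3 corepressor complex, lipid synthesis and storage, p53 targets, the interferon response, stress genes, Y-linked genes, X-linked genes expressed after meiosis, mitochondrially encoded mRNAs, replication-dependent histones and cytosolic ribosomal proteins. Of these, 23 could be tested in each cell type. The mitochondrial list had 0 symbols in the tables, and 1 of the 7 listed red blood cell genes passed the filter. For the relation of the KO effect to the step from PS to RS, which share control libraries, unchanged KO libraries were simulated 20 times.

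Genes were named by a fixed rule. For each KO comparison these were Hdac3 and the 5 largest rises and 5 largest falls among genes that passed, had a mean of at least 5 CPM in the higher group and had every library of the higher group above every library of the lower, leaving out predicted and clone names. From each list the 2 members with the smallest adjusted p among those that rose and the 2 among those that fell were named, or, in a list with no member past the threshold, the 2 with the highest mean CPM, as values. For the interaction and the control cell types the 3 largest changes in each direction under the same conditions were named. Multicopy or paralogous genes are named as uncertain. Some genes that the rule selects are not reported here by name and remain in the counts. Coordinates come from GENCODE M21 on GRCm38, the assembly that mm10 names, which held 21025 of the symbols (98.1%).

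The alternative settings were relative log expression size factors, library size as the only scaling, no filter beyond a total count above 0, at least 10 counts in every library of 1 group, DESeq2 1.42.0, limma-voom, the replicate number as a block, 1 fit of 12 libraries, other thresholds, other fold limits for the stage lists, each library left out, and all remaining replicates left out. A trend with transcript length and GC content removed per library, alone and with the block, was added after the data were seen. Scripts were tested on simulated counts with these libraries' means and sizes and 50 genes changed at each fold. In PS (15272 genes) 4%, 50%, 84% and 100% of genes changed 1.5-, 2-, 4- and 8-fold were called, with 7.69% of calls false. In RS (15934) the shares were 2%, 18%, 84% and 88%, with 7.69% false. For the interaction and the control cell types (16581 genes) they were 0%, 12%, 70% and 82% (5.68% false) and 4%, 30%, 82% and 96% (7.02% false). With the block 8.66% of calls in PS and 14.7% in RS were false. In each simulation camera called the changed set of 40 genes and 0 of 20 unchanged sets. Other splits of real libraries gave up to 14 lists (PS) and 16 (RS). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.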

Results

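RNA was sequenced from 2 germ cell types of mouse testes. Pachytene spermatocytes (PS) are meiotic cells of mid-prophase, and round spermatids (RS) are the haploid cells that follow the meiotic divisions. Control mice carried a floxed and a normal Hdac3 allele (Hdac3fl/+). Knockout (KO) mice carried a floxed and a null allele together with Stra8-cre (Stra8-cre/Hdac3fl/-), a transgene that makes Cre recombinase in germ cells before meiosis. HDAC3 is a histone deacetylase that acts within nuclear receptor corepressor complexes. Each of the 4 groups had 3 libraries. In PS the total gene counts of replicates 1, 3 and the remaining replicate were 17467583, 16842756 and 12137427 in controls and 17172187, 17049209 and 13438386 in KO. In RS they were 17168813, 17393447 and 13089105 in controls and 17048477, 17270003 and 11205732 in KO. The remaining replicate of each group, tied to its group and not to 1 sample title, was the shallowest.

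The targeted gene, Hdac3 (chromosome 18, 37935844 to 37955016, minus strand, GRCm38), fell in KO cells of both types. In PS it was at 61.2, 52.3 and 81.7 CPM (counts scaled to the library total) in the control libraries and at 18.3, 18.1 and 25.1 CPM in the KO libraries, a log2 fold change of -1.67 (SE 0.217, adjusted p = 0.00558, edgeR). In RS the control libraries held 42.1, 48.5 and 52.7 CPM and the KO libraries 13.4, 14.1 and 17.2 CPM, a log2 fold change of -1.68 (SE 0.186, adjusted p = 0.00249, edgeR). Without both remaining libraries the fall in RS was -1.72 and did not pass (adjusted p = 0.0793, edgeR). The authors' deposited table gave -1.74 in PS and -1.82 in RS. Counts were made over the whole gene, and the sources used here do not say which exons Cre removes.

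The first comparison asked which transcripts differ between KO and control PS. The lists of protamines, acrosome, flagellum and sperm energy metabolism fell in KO PS libraries, where spermatid RNA was not told apart. Members included Prm2, a sperm protamine, Odf1, of the outer dense fibres of the sperm tail, and Akap4, of the fibrous sheath. Prm2 went from 799 ± 328 to 216 ± 81.7 CPM (SD, n = 3), a log2 fold change of -1.89 (SE 0.320, adjusted p = 0.00700). Odf1 went from 209 ± 57.7 to 69.1 ± 20.1 CPM (log2 fold change -1.60, SE 0.237, adjusted p = 0.00558), and Akap4 from 342 ± 50.5 to 144 ± 36.2 CPM (-1.25, SE 0.201, adjusted p = 0.00582). Stra8, the retinoic acid responsive gene of meiotic entry, rose from 5.83 ± 1.79 to 17.2 ± 1.88 CPM (1.56, SE 0.277, adjusted p = 0.00826). The KO label names a transgene with the Stra8 promoter and the control label does not, so any Stra8 sequence transcribed from it would count as Stra8.

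The largest rise in KO PS under the naming rule was that of Igfbp3, an insulin-like growth factor binding protein (chromosome 11, 7206086 to 7213923; log2 fold change 3.77, SE 0.545). Ntn4, a netrin of basement membranes (chromosome 10, 93640681 to 93747207), followed at 2.36 (SE 0.413). Rnf208 (chromosome 2, 25242255 to 25244262) was at 2.29 (SE 0.307). Ttn, the giant sarcomere protein titin (chromosome 2, 76703980 to 76982547), was at 2.11 (SE 0.336), and Srms, a non-receptor tyrosine kinase (chromosome 2, 181205562 to 181213185), at 1.86 (SE 0.292). The largest fall was that of Myh11, the smooth muscle myosin heavy chain (chromosome 16, 14194535 to 14291372; -2.42, SE 0.545). Tppp2, of the tubulin polymerization promoting family (chromosome 14, 51918425 to 51920700), was at -2.31 (SE 0.410), and Fmn2, an actin nucleating formin (chromosome 1, 174501825 to 174822729), at -2.14 (SE 0.342). Abcg8, a subunit of a sterol transporter (chromosome 17, 84676302 to 84700333), was at -2.11 (SE 0.344), and Cyp26b1, which degrades retinoic acid (chromosome 6, 84571414 to 84593908), at -2.05 (SE 0.530). The adjusted p values of these 10 genes ranged from 0.00558 to 0.0394 (edgeR). Igfbp3 was at 0.507 ± 0.164 CPM in control and 6.95 ± 5.04 CPM in KO PS. Without KO replicate 3 the adjusted p of Myh11 was 0.0706, and that of Cyp26b1 was at most 0.121 without KO replicate 1, KO replicate 3 or the remaining control.

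In all, 826 of 15272 genes tested changed in KO PS (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 139 higher and 687 lower. Of these, 95 were higher and 500 lower by more than 2-fold, and all 826 moved the called way in all 3 pairs of control and KO libraries. With the replicate number as a block, 3476 genes passed, 1623 higher and 1853 lower. The count was 407 without control replicate 3, 1592 without the remaining control, 304 without KO replicate 1 and 288 without KO replicate 3. The ribosomal transcript Rn45s took more of the counts in the KO than in the control library of each pair, 0.0449% against 0.0320%, 0.0609% against 0.0416% and, in the remaining pair, 0.271% against 0.0462% (log2 fold change 1.65, adjusted p = 0.0569, 0.0173 with the replicate block).

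Of the lists of spermatid products, all 4 fell in KO PS. Among transition proteins, protamines and testis linker histones, 8 of 16 tested members fell and 0 rose (12 fell adjusted over the list alone). The median log2 fold change was -1.33 (camera adjusted p = 4.31e-06), and 0 members rose at an unadjusted p under 0.05 or by DESeq2 or voom. H1fnt, a linker histone of spermatids, was at 111 ± 18.6 CPM in control and 38.6 ± 9.93 CPM in KO PS (-1.52, SE 0.208, adjusted p = 0.00558). Of 35 acrosome genes, 15 fell (20 fell and 1 rose adjusted over the list alone), with a median of -0.63 (camera adjusted p = 4.19e-07). They included Eqtn, a protein of the acrosomal membrane (-1.22, SE 0.220, adjusted p = 0.00855), and Capza3, a sperm actin capping subunit (-0.96, SE 0.193, adjusted p = 0.0120). Of 45 genes of the flagellum and fibrous sheath, 14 fell (20 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 6.44e-09). One of them was the spermatid kinase gene Tssk3 (-1.34, SE 0.207, adjusted p = 0.00558). Of 20 genes of sperm energy metabolism, 5 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 0.00455). Here Hk1, the hexokinase of sperm, went from 662 ± 38.7 to 317 ± 45.2 CPM (-1.07, SE 0.169, adjusted p = 0.00567). The aldolase retrogene Aldoart1, which shares sequence with Aldoa, fell (-1.24, SE 0.207, adjusted p = 0.00645), while Tpi1, triose phosphate isomerase, rose (0.83, SE 0.157, adjusted p = 0.00943). Each of these 4 list calls was lost (adjusted p = 0.698 with an estimated correlation). Capza3 was at an adjusted p of at most 0.0565 without KO replicate 1 or KO replicate 3, and Tpi1 at 0.0571 without control replicate 3. With the block 13, 20, 26 and 12 members of the protamine, acrosome, flagellum and energy lists fell and 1, 2, 0 and 3 rose. The members that fell numbered 6, 3, 11 and 4 without control replicate 3, 2, 1, 9 and 3 without KO replicate 1 and 4, 2, 6 and 2 without KO replicate 3. They numbered 4, 18, 25 and 10 without the remaining control, 3 energy genes fell without control replicate 1, and 3 members of the protamine list fell with library size only. The energy median was -0.23 without control replicate 3 and -0.18 with a trend with transcript length and GC content removed, and the acrosome median was -0.41 with that trend removed.

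**Figure D1:**
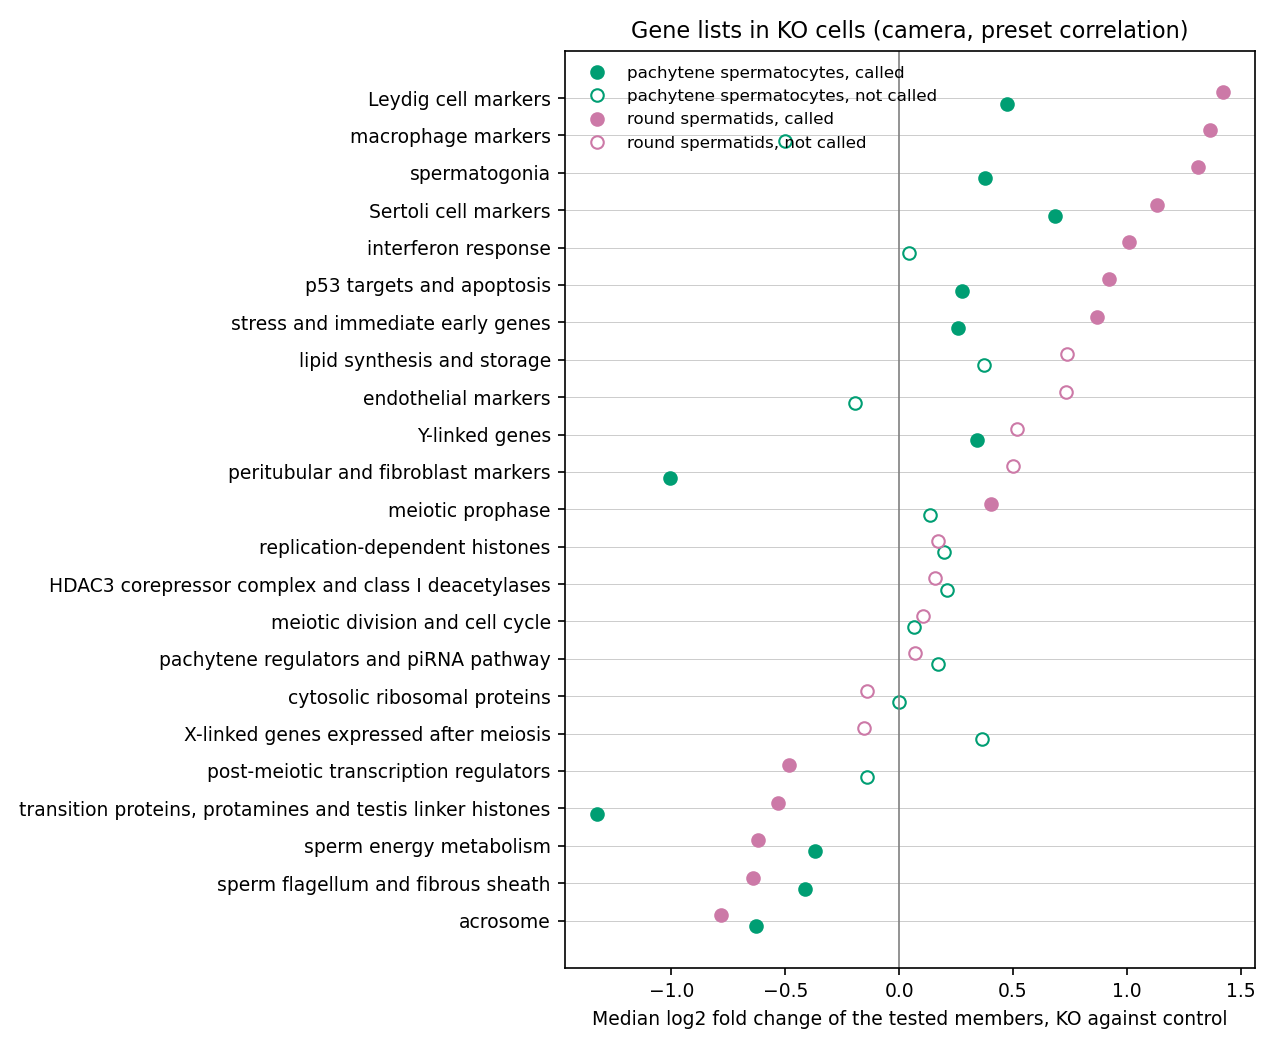
Median log2 fold change (KO against control, horizontal axis) of each gene list in PS and RS, with list names on the vertical axis and filled points for lists past the camera test. The acrosome, flagellum and sperm energy lists lay below 0 in both cell types, at -0.63, -0.41 and -0.37 in PS and at -0.78, -0.64 and -0.62 in RS.

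Regulators of meiosis and of spermatid transcription moved in both directions in KO PS, and none of their lists passed as a group. Of 18 post-meiotic transcription regulators, 1 rose and 3 fell (3 and 4 adjusted over the list alone; median -0.14, camera adjusted p = 0.249). Fhl5 (ACT), a testis coactivator of CREM, fell (-1.18, SE 0.222, adjusted p = 0.00951). So did Spz1, a bHLH-Zip transcription factor, which went from 251 ± 44.4 to 94.2 ± 31.8 CPM (adjusted p = 0.00592). Taf7l, a germ cell TFIID subunit, rose (0.85, SE 0.217, adjusted p = 0.0366). Of 35 meiotic prophase genes, 1 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.14, camera adjusted p = 0.136). The one that fell was Rec8, a meiotic cohesin subunit (-0.71, SE 0.176, adjusted p = 0.0334). Of 22 pachytene regulators and piRNA pathway genes, Tdrd5, a tudor domain protein, rose (0.72, SE 0.191, adjusted p = 0.0444) and Kif17, a kinesin that binds ACT, fell (-0.69, SE 0.180, adjusted p = 0.0423). Adjusted over the list alone, 3 rose and 1 fell (median 0.17, camera adjusted p = 0.0928). Of 31 genes of the meiotic divisions, 1 rose (0 adjusted over the list alone; median 0.07, camera adjusted p = 0.521), the cyclin gene Ccnb3 (1.75, SE 0.463, adjusted p = 0.0445). The prophase and piRNA lists passed without the remaining KO library (camera adjusted p = 0.0337 and 0.00828, both upward). The calls of Taf7l and Ccnb3 ended without any 1 of 5 libraries (all but the remaining control), with adjusted p values of up to 0.162 and 0.169. Those of Rec8, Kif17 and Tdrd5 ended without any 1 of 4 (replicates 1 and 3 of both groups), with up to 0.135, 0.176 and 0.212. With the block 3 post-meiotic regulators rose and 5 fell, 6 prophase genes rose and 1 fell, 6 piRNA pathway genes rose and 1 fell, and 4 division genes rose and 1 fell. Without the remaining control 3 prophase and 3 piRNA pathway genes rose and 1 division gene fell, and without the remaining KO library 2 piRNA pathway genes rose. With the trend removed 4 prophase and 2 division genes rose.

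Markers of other cells of the testis also differed between KO and control PS. Peritubular and fibroblast markers fell as a list, with 3 of 14 lower (7 lower and 1 higher adjusted over the list alone), a median of -1.01 and a camera adjusted p of 0.00180 (0.0540, with a median of -0.50, without the remaining control). With the block 5 were lower and 1 higher, with the trend removed 4 and 1, and without KO replicate 3 or with library size only 1 was lower. They included Actg2, an enteric smooth muscle actin that shares sequence with other actins (55.3 ± 6.75 to 24.0 ± 7.47 CPM; -1.21, SE 0.227, adjusted p = 0.00943). Sertoli cell markers rose as a list (median 0.68, camera adjusted p = 5.41e-05). Spermatogonial genes (median 0.38, camera adjusted p = 0.00586) and Leydig cell markers (median 0.47, camera adjusted p = 0.0295) also rose. The Leydig call ended without control replicate 1 (0.128), control replicate 3 (0.0937) or the remaining KO library (0.227). With the block 18 of 21 Sertoli, 5 of 22 spermatogonial and 6 of 12 Leydig members were called, all higher. Without the block edgeR called 0 of each, with 7, 6 and 3 higher at an unadjusted p under 0.05, and 9, 4 and 1 were called higher without the remaining control. With the trend removed 8, 1 and 2 rose. The Sertoli median was 0.41, 1.11 and 0.29 without control replicate 1, the remaining control and the remaining KO library, the spermatogonial median 0.60 and 0.18 without these remaining libraries, and the Leydig median 0.31 and 0.23 without control replicate 1 and the remaining KO library. DESeq2 and voom each called 1, 1 and 0 of the 3 lists, and 5, 0 and 0 were higher adjusted over the list alone. The most abundant Sertoli marker, Clu, was at 460 ± 250 CPM in control and 733 ± 296 CPM in KO PS (0.67, SE 0.329, adjusted p = 0.267, 0.000441 with the replicate block), and the Leydig enzyme gene Cyp17a1 was at 224 ± 83.8 and 222 ± 84.8 CPM (adjusted p = 0.989). Macrophage markers (0 of 11 called, 1 lower at an unadjusted p under 0.05, 1 lower with the block; median -0.50, or 0.29 without the remaining control; camera adjusted p = 0.265) and endothelial markers (0 of 9, 0 at an unadjusted p under 0.05; median -0.19, camera adjusted p = 0.249) did not pass. DESeq2 and voom called 0 members of either, and 0 were called adjusted over the list alone. The most abundant members of these lists that are not given above were Amhr2 (0.46, adjusted p = 0.467, 0.0102 with the replicate block), Fabp3 (0.49, adjusted p = 0.234, 0.00766 with the block), Dmrtb1 (-0.06), Id4 (0.15), Mrc1 (0.00), H2-Ab1 (0.55), Cdh5 (0.06) and Cldn5 (-0.23), given as log2 fold changes that did not pass. The endothelial list passed downward without the remaining KO library (0.000303). The lists called here were lost with adjusted p = 0.698 with an estimated correlation.

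The other lists fixed in advance held few calls in KO PS. The list of p53 targets rose (0 of 18 members called, 5 higher at an unadjusted p under 0.05; median 0.28, camera adjusted p = 0.0451). So did stress and immediate early genes (0 of 20, 3 higher at an unadjusted p under 0.05; median 0.26, camera adjusted p = 0.0115) and Y-linked genes (0 of 8, 2 higher at an unadjusted p under 0.05; median 0.34, camera adjusted p = 0.0451). Each call was lost (adjusted p = 0.698 with an estimated correlation). DESeq2 called 0, 1 and 1 members of these, voom 0 of each, and 0, 0 and 2 rose adjusted over the list alone. With the block 4 p53, 4 stress and 2 Y-linked genes rose, and without the remaining control 4, 3 and 1. The p53 median was 0.14, 0.43 and 0.08 without control replicate 3, the remaining control and the remaining KO library, and the stress median 0.14, 0.15, 0.59 and 0.12 without control replicate 1 and these libraries. The p53 call ended without control replicate 1 (0.0560), control replicate 3 (0.165) or the remaining KO library (0.185). The stress call ended without control replicate 1 (0.0795) or control replicate 3 (0.0822), and the Y-linked call ended without the remaining control (0.134), KO replicate 1 (0.0928) or the remaining KO library (0.0740) and with the replicate block (0.09999). Of 19 genes of lipid synthesis and storage, Fasn, fatty acid synthase, rose (90.1 ± 19.9 to 163 ± 26.0 CPM; 0.86, SE 0.195, adjusted p = 0.0212) and none fell (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0877, 0.0497 with the replicate block, 0.0198 without KO replicate 3). With the block 8 rose and 2 fell, without the remaining control 4 and 1, and with the trend removed 2 and 1. Of 13 genes of the HDAC3 corepressor complex and class I deacetylases, Hdac3 alone was called, over all genes and adjusted over the list alone (camera adjusted p = 0.516). Akap4 was the 1 called member, in both ways, of 14 X-linked genes expressed after meiosis (camera adjusted p = 0.443). Hist1h4h, one of many near-identical histone H4 genes, was that of 16 replication-dependent histones (1.63, SE 0.428, adjusted p = 0.0425; camera adjusted p = 0.255). With the block 4 corepressor genes rose and 2 fell, 2 X-linked genes rose and 2 fell, 2 histone genes rose, and 4 ribosomal genes rose and 1 fell. With the trend removed 2 stress and 2 histone genes rose. The interferon list (0 of 17, 0 at an unadjusted p under 0.05; camera adjusted p = 0.893) and the cytosolic ribosomal list (0 of 79, 2 higher and 1 lower at an unadjusted p under 0.05; camera adjusted p = 0.861) did not pass. DESeq2 and voom called 0 members of either, and 0 were called adjusted over the list alone. Of the most abundant members of the lists without a call, Ddit3 (0.57, adjusted p = 0.0592) and Mdm2 (0.37, adjusted p = 0.233) passed with the replicate block (0.00265 and 0.0123), and Dnajb1 (0.20), Zmat3 (-0.05), Stat2 (-0.10), Eif2s3y (-0.02), Uba1y (0.26), Rplp0 (-0.09) and Rpl4 (0.21) did not pass (log2 fold changes). The ribosomal list passed downward without control replicate 1 (0.0360) and KO replicate 3 (0.0132) and upward without KO replicate 1 (0.0235), and its mean (0.01) and median (-0.00105) differed in sign. Of the red blood cell list only Alas2 was tested (-0.52, SE 0.437, adjusted p = 0.547). Fasn was at adjusted p values of up to 0.108 without control replicate 1, control replicate 3 or KO replicate 1, and Hist1h4h of up to 0.202 without any 1 library but KO replicate 1.

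The second comparison asked the same question of RS. In KO RS, macrophage markers and genes of spermatogonia and p53 signalling rose as lists, and genes of the acrosome, flagellum and sperm energy metabolism fell. Cd74, the invariant chain of MHC class II and a member of the macrophage list, went from 7.257 ± 3.602 to 55.3 ± 4.52 CPM (SD, n = 3; log2 fold change 2.93, SE 0.317, adjusted p = 0.00249), and Kit, the stem cell factor receptor of spermatogonia, from 15.0 ± 1.77 to 41.5 ± 7.27 CPM (1.46, SE 0.197, adjusted p = 0.00303). Eqtn went from 174 ± 37.4 to 75.1 ± 4.47 CPM (-1.21, SE 0.193, adjusted p = 0.00420). Tbl1x, an X-linked subunit of the HDAC3 corepressor complex, went from 2.92 ± 0.643 to 13.9 ± 1.07 CPM (2.24, SE 0.251, adjusted p = 0.00249). Stra8 rose from 20.02 ± 7.084 to 55.1 ± 6.14 CPM (1.46, SE 0.261, adjusted p = 0.00561), with the same limit from the transgene as in PS.

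The largest rise in KO RS was that of Mgl2, a lectin of macrophages and dendritic cells (chromosome 11, 70130329 to 70137550; log2 fold change 5.45, SE 0.569). H2-Eb1 (chromosome 17, 34305867 to 34316674) and H2-Aa (chromosome 17, 34282744 to 34287823), which encode MHC class II chains, were at 2.94 (SE 0.435) and 2.73 (SE 0.452). Cd74 (chromosome 18, 60803848 to 60812652) is given above, and Plk5, a polo-like kinase (chromosome 10, 80356459 to 80365489), was at 2.70 (SE 0.393). Mgl2 had 0, 4 and 2 counts in the control libraries, and the ratio of its pooled CPM was 55.8 (95% counting interval 25.4 to 153, counting error only). The largest fall was that of Fcmr, the Fc receptor of IgM (chromosome 1, 130865669 to 130880791; -2.23, SE 0.588). Col9a1, a collagen IX chain (chromosome 1, 24177610 to 24252684), was at -2.01 (SE 0.294). Agr3, a protein disulfide isomerase (chromosome 12, 35925620 to 35949736), was at -1.94 (SE 0.432), and Abcg8 at -1.93 (SE 0.379). Nudt12os (chromosome 17, 58996251 to 59024981) was at -1.88 (SE 0.374). It is an antisense transcript whose reads cannot be told from those of its partner without strand. The adjusted p values of these 10 genes ranged from 0.00249 to 0.0198 (edgeR). Fcmr was at an adjusted p of at most 0.0837 without control replicate 3 or the remaining KO library, and Agr3 at 0.0547 without the latter.

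In all, 4942 of 15934 genes tested changed in KO RS, 2974 higher and 1968 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 2146 were higher and 542 lower by more than 2-fold, and 4928 moved the called way in all 3 pairs. The share of calls that were higher, 60.2%, was 84.5% with library size as the only scaling, which moved the median of all genes from 0.02 to 0.27 (log2), and 44.1% with a trend with transcript length and GC content removed. With the replicate block 8736 genes passed, 4582 higher and 4154 lower. The count was 2933 without control replicate 3, 3116 without the remaining control, 2947 without KO replicate 3 and 1546 without the remaining KO library. Without both remaining libraries edgeR called 0 genes, with 4103 at an unadjusted p under 0.05, while DESeq2 called 1052 and voom 0. Rn45s again took more of the counts in each KO library than in its control, 0.0341% against 0.0270%, 0.113% against 0.0586% and, in the remaining pair, 0.276% against 0.0892% (log2 fold change 0.98, adjusted p = 0.223, 0.00763 with the replicate block).

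**Figure D2:**
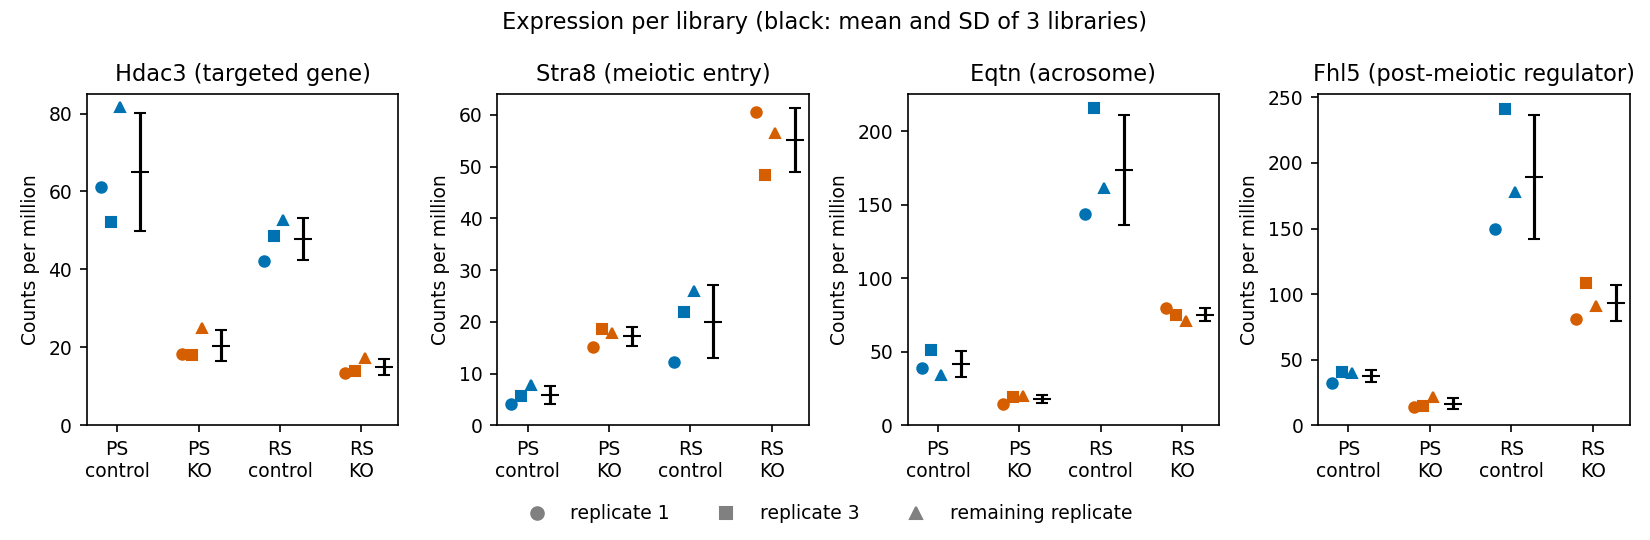
CPM (vertical axis) of Hdac3, Stra8, Eqtn and Fhl5 in each of the 12 libraries by group, with the mean and SD of 3 libraries. Hdac3 lay at 52.3 to 81.7 CPM in control PS and 18.1 to 25.1 CPM in KO PS, and every KO library lay below every control library of its cell type for Hdac3, Eqtn and Fhl5 and above for Stra8.

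Genes of sperm structures fell in KO RS as they did in KO PS. Of 35 acrosome genes, 25 fell and 1 rose (28 and 1 adjusted over the list alone), with a median of -0.78 (camera adjusted p = 6.98e-09, adjusted p = 0.559 with an estimated correlation). They included Hyal5, a sperm hyaluronidase (-1.08, SE 0.178, adjusted p = 0.00455), and the one that rose was Gopc, a Golgi protein needed for acrosome formation (0.59, SE 0.196, adjusted p = 0.0449). Of 45 flagellar genes, 21 fell (26 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 6.98e-09, adjusted p = 0.407 with an estimated correlation). They included the sperm calcium channel gene Catsper3 (-1.08, SE 0.182, adjusted p = 0.00475) and Odf3 (-1.02, SE 0.181, adjusted p = 0.00559). Of 20 genes of sperm energy metabolism, 9 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of -0.62 (camera adjusted p = 0.000551, adjusted p = 0.407 with an estimated correlation). Acot10, an acyl-CoA thioesterase close in sequence to Acot9 (-1.25, SE 0.187, adjusted p = 0.00353), and the glycerol kinase retrogene Gykl1 (-0.82, SE 0.174, adjusted p = 0.00938) fell, and Slc25a31, an ADP/ATP carrier, rose (0.67, SE 0.186, adjusted p = 0.0231). Of 16 members of the list of transition proteins, protamines and testis linker histones, 3 fell and 1 rose in both ways of adjusting, with a median of -0.53 (camera adjusted p = 0.0368, adjusted p = 0.7499 with an estimated correlation). The list call was lost without control replicate 3 (0.128) or KO replicate 1 (0.219). The called members included Spaca7, an acrosomal protein (-0.97, SE 0.212, adjusted p = 0.0102), Camk4, a kinase of protamine 2 (-0.82, SE 0.181, adjusted p = 0.0106), and Ubr2, a ubiquitin ligase, which rose (1.21, SE 0.217, adjusted p = 0.00567). Gopc lost its call whichever 1 library was left out (up to 0.140), and Slc25a31 without any 1 of 4 (control replicate 1, KO replicate 3 and both remaining libraries, up to 0.0883). Gykl1 (0.0503) and Spaca7 (0.0525) lost theirs without the remaining KO library. With the block 38 flagellar genes fell, 15 energy genes fell and 2 rose, and 10 members of the protamine list fell. The acrosome, flagellum, energy and protamine lists had 16, 13, 4 and 3 members lower without KO replicate 3 and 11, 10, 2 and 1 without the remaining KO library, and the energy list 5 without the remaining control. With library size only 15, 16, 3 and 1 members fell, 2 energy genes rose, and the medians were -0.52, -0.36, -0.34 and -0.27. The protamine median was also -0.21 without control replicate 3 and -0.21 with the trend removed, where 5 of its members fell.

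Of 18 post-meiotic transcription regulators, 8 fell and 1 rose in both ways of adjusting, with a median of -0.48 (camera adjusted p = 0.0157, adjusted p = 0.645 with an estimated correlation). Fhl5 went from 190 ± 47.2 to 93.4 ± 13.9 CPM (-1.02, SE 0.216, adjusted p = 0.00941). Sox5, an SRY-related factor, went from 250 ± 40.2 to 129 ± 13.7 CPM (-0.96, SE 0.185, adjusted p = 0.00704), and Taf7l rose (0.95, SE 0.198, adjusted p = 0.00900). Of 36 meiotic prophase genes, 11 rose and 1 fell (12 and 2 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.0307, adjusted p = 0.7499 with an estimated correlation). The list call was lost without control replicate 1 (0.118) or KO replicate 3 (0.0571). Tex11, an X-linked crossover protein, rose from 20.5 ± 4.10 to 51.1 ± 5.93 CPM (1.32, SE 0.200, adjusted p = 0.00367), and Rec8 fell (-0.75, SE 0.202, adjusted p = 0.0210). The meiotic division list (3 of 31 higher, 1 adjusted over the list alone; camera adjusted p = 0.870) and the piRNA pathway list (5 of 22 higher and 1 lower, 4 and 1 adjusted over the list alone; camera adjusted p = 0.885) did not pass as lists. Their members that rose included Ccnb3 (1.39, SE 0.271, adjusted p = 0.00714) and the mitotic and meiotic kinase gene Aurkb (0.70, SE 0.201, adjusted p = 0.0267). Tdrkh (0.87, SE 0.199, adjusted p = 0.0118) and Mov10l1, the piRNA helicase (62.0 ± 13.2 to 112 ± 24.3 CPM, adjusted p = 0.0184) also rose, and Gtsf1 fell (-0.85, SE 0.237, adjusted p = 0.0240). With single libraries left out, the highest adjusted p was 0.0943 for Rec8 (lost without KO replicate 3 or either remaining library) and 0.112 for Aurkb (lost without any library but KO replicate 1). It was 0.0577 for Tdrkh (the remaining KO library), 0.0867 for Mov10l1 (control replicate 3 or the remaining KO library) and 0.0993 for Gtsf1 (control replicate 3 or either remaining library). With the block 18 prophase genes rose and 5 fell, 9 division genes rose and 3 fell, and 7 piRNA pathway genes rose and 6 fell. Without control replicate 3, the remaining control, KO replicate 3 and the remaining KO library 4, 4, 4 and 2 post-meiotic regulators fell and 1 division gene rose in each. Prophase genes that rose numbered 7 without control replicate 1, control replicate 3 or KO replicate 3 and 6 without the remaining KO library. At most 3 piRNA pathway genes rose without control replicate 1, control replicate 3, KO replicate 3 or the remaining KO library, and 5 fell without KO replicate 1. With the trend removed 3 fell, 4 rose, and 2 prophase genes and 1 division gene fell. With library size only 3 post-meiotic regulators fell and 2 rose (median -0.22), and 19 prophase and 9 division genes rose (medians 0.65 and 0.37).

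Spermatogonial genes and the markers of several somatic cell types rose in KO RS. Of 24 spermatogonial genes, 16 rose (18 adjusted over the list alone), with a median of 1.31 (camera adjusted p = 1.13e-05, adjusted p = 0.559 with an estimated correlation). Next to Kit stood Dmrt1, a transcription factor of spermatogonia and Sertoli cells, at 16.1 ± 3.37 and 46.0 ± 9.36 CPM (1.52, SE 0.227, adjusted p = 0.00353). Of 15 macrophage markers, 13 rose (14 adjusted over the list alone), with a median of 1.36 (camera adjusted p = 1.66e-06, adjusted p = 0.407 with an estimated correlation). They included H2-Ab1 (9.41 ± 3.49 to 35.4 ± 5.17 CPM; 1.91, SE 0.272, adjusted p = 0.00315). Of 18 Sertoli cell markers, 6 rose (8 adjusted over the list alone), with a median of 1.13 (camera adjusted p = 0.0197, 0.151 without KO replicate 3, adjusted p = 0.757 with an estimated correlation). Trf, transferrin, was at 4.97 ± 0.684 and 14.3 ± 3.85 CPM (1.52, SE 0.269, adjusted p = 0.00558), and Kitl, the KIT ligand, rose (1.73, SE 0.423, adjusted p = 0.0150). Of 11 Leydig cell markers, 3 rose (6 adjusted over the list alone, 6 by DESeq2 and 0 by voom), with a median of 1.42 (camera adjusted p = 0.0482, adjusted p = 0.757 with an estimated correlation). They included Hsd3b6 (2.16, SE 0.572, adjusted p = 0.0200) and Hsd3b1 (1.83, SE 0.536, adjusted p = 0.0289), near-identical steroid dehydrogenase genes. The Leydig call ended without control replicate 1 (0.118), control replicate 3 (0.149), KO replicate 3 (0.196) or the remaining KO library (0.104). With the block 10 Sertoli and 7 Leydig markers rose, and 6 peritubular markers rose and 2 fell. With the trend removed 5 Leydig markers rose, and with library size only 2 peritubular markers. Without KO replicate 3 the members called were 1 of 18 for Sertoli cells (median 0.65), 0 of 11 for Leydig cells (median 0.87, 2 higher at an unadjusted p under 0.05) and 11 of 15 for macrophages. Without the remaining KO library 8 spermatogonial genes, 8 macrophage markers and 1 Sertoli marker rose. Sertoli markers that rose numbered 3, 2 and 2 of 20 without control replicate 1, control replicate 3 and the remaining control. Without KO replicate 1 they numbered 14 of 20, with 9 Leydig, 5 endothelial and 4 peritubular markers higher. EdgeR called 0 Leydig markers without control replicate 3 or the remaining KO library, with 4 and 5 higher at an unadjusted p under 0.05. Of 9 endothelial markers 1 rose (0 adjusted over the list alone), Esam (1.64, SE 0.509, adjusted p = 0.0352; camera adjusted p = 0.462, 0.0173 without KO replicate 1). Of 15 peritubular markers edgeR called 0, with 2 higher and 1 lower at an unadjusted p under 0.05, 0 by DESeq2 or voom and 0 adjusted over the list alone (camera adjusted p = 0.703). Its most abundant members, Actg2 (-0.53, adjusted p = 0.0928) and Dcn (0.64, adjusted p = 0.110), passed with the replicate block (0.00637 and 0.0456). The red blood cell marker Alas2 was at -0.36 (SE 0.588, adjusted p = 0.646). With single libraries left out, the highest adjusted p was 0.0644 for Kitl (lost without KO replicate 3 or either remaining library). It was 0.0658 for Hsd3b6 (control replicate 3, KO replicate 3, remaining KO library), 0.103 for Hsd3b1 (those and control replicate 1) and 0.160 for Esam (any library but KO replicate 1).

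**Figure D3:**
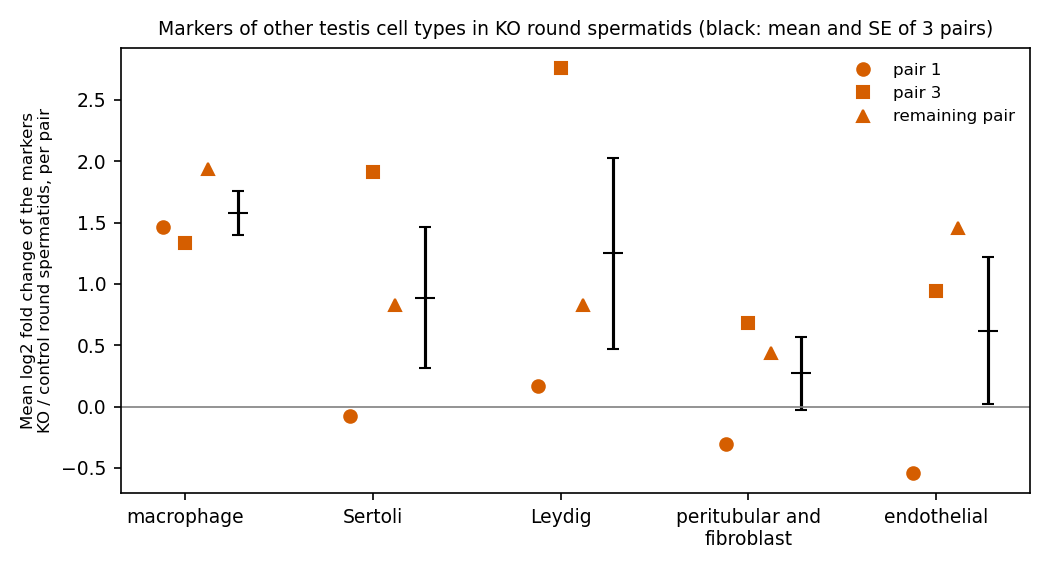
Mean log2 fold change (KO against control RS, vertical axis) of the marker lists of 5 somatic cell types in each of the 3 pairs of libraries, with the mean and SE of the pairs. Macrophage markers lay at 1.47, 1.93 and 1.33 in the pairs, while Leydig cell markers lay at 0.16, 0.83 and 2.76 and peritubular markers at -0.31, 0.43 and 0.68.

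Genes of stress and signalling pathways rose in KO RS, in the same libraries as the macrophage markers (median 1.36). Of 18 p53 targets, 9 rose (11 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 0.000551, adjusted p = 0.407 with an estimated correlation). They included Trp53inp1, a p53 cofactor (9.15 ± 0.733 to 29.7 ± 3.50 CPM, adjusted p = 0.00249), and Ccng1, cyclin G1 (1.69, SE 0.222, adjusted p = 0.00298). Of 17 interferon response genes, 6 rose in both ways of adjusting, with a median of 1.01 (0.65 with the trend removed; camera adjusted p = 0.0157, adjusted p = 0.645 with an estimated correlation). They included Irf9 (1.69, SE 0.289, adjusted p = 0.00505) and Stat2 (1.08, SE 0.297, adjusted p = 0.0225), partners in the interferon transcription factor. Of 20 stress and immediate early genes, 8 rose (15 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 0.00418, adjusted p = 0.674 with an estimated correlation). They included Gadd45b (1.33, SE 0.247, adjusted p = 0.00625) and Zfp36, an mRNA decay factor (1.11, SE 0.275, adjusted p = 0.0155). The lipid list had 7 of 19 members higher and 3 lower (7 and 4 adjusted over the list alone) and did not pass as a list (camera adjusted p = 0.253). Acly, ATP citrate lyase (24.0 ± 1.48 to 63.3 ± 14.1 CPM; 1.40, SE 0.197, adjusted p = 0.00313), and Srebf1, the master regulator of lipid synthesis (1.15, SE 0.190, adjusted p = 0.00451), rose, and the lipid storage genes Plin2 (-1.03, SE 0.167, adjusted p = 0.00433) and Dgat2 (-0.73, SE 0.160, adjusted p = 0.0102) fell. The p53 targets that rose numbered 5 without any 1 of control replicate 3, the remaining control, KO replicate 3 and the remaining KO library. Interferon genes that rose numbered 3, 2 and 1 of 22 without control replicate 1, control replicate 3 and the remaining control, 10 of 22 without KO replicate 1, and 2 and 1 without KO replicate 3 and the remaining KO library. Stress genes that rose numbered 17 with the replicate block, 17 without KO replicate 1, 3 without control replicate 3, the remaining control or KO replicate 3 and 1 without the remaining KO library, and 15 with library size only. Without the remaining KO library 4 lipid genes rose and 1 fell, Zfp36 was at an adjusted p of 0.0767 and Dgat2 at 0.0502, and Stat2 at up to 0.107 without control replicate 3 or either remaining library.

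Of 14 genes of the HDAC3 corepressor complex and class I deacetylases, 2 rose in KO RS, among them Tbl1x, and Hdac3 fell, in both ways of adjusting (camera adjusted p = 0.885). Of 8 Y-linked genes 3 rose in both ways of adjusting (camera adjusted p = 0.220), among them Ddx3y, a helicase gene (1.32, SE 0.214, adjusted p = 0.00436), and Kdm5d, a demethylase gene (1.36, SE 0.368, adjusted p = 0.0218). Both share sequence with X-linked copies. Of 15 X-linked genes expressed after meiosis 2 rose in both ways of adjusting, Mageb4 (1.66, SE 0.215, adjusted p = 0.00298) and Tex16 (1.20, SE 0.212, adjusted p = 0.00558), and the list did not pass (median -0.15, mean 0.01, camera adjusted p = 0.703). Of 16 replication-dependent histones 1 fell in both ways of adjusting, Hist1h2bp, one of many near-identical histone H2B genes (-1.02, SE 0.244, adjusted p = 0.0139), while the list median was 0.17 and camera pointed downward (adjusted p = 0.885). Of 80 cytosolic ribosomal protein genes 4 rose (0 adjusted over the list alone; median -0.14, camera adjusted p = 0.703, 0.00276 downward without control replicate 1). They included Rpl10, which has many processed copies (1.23, SE 0.317, adjusted p = 0.0181), and Rpl3l, a paralog of Rpl3 with 48 counts in KO and 9 in control libraries (ratio of CPM 5.58, 95% counting interval 2.71 to 12.9). With the block 4 corepressor genes rose and 2 fell, 5 Y-linked genes rose, 3 X-linked genes rose and 5 fell, 1 histone gene rose and 2 fell, and 12 ribosomal genes rose and 11 fell. Without control replicate 1, the remaining control or the remaining KO library 1 Y-linked gene rose, and without control replicate 3 or either remaining library 1 corepressor gene. With library size only 5 Y-linked and 4 corepressor genes rose. With the trend removed 2 Y-linked genes rose and 1 fell (median 0.24 against 0.52), 1 corepressor gene rose and 2 fell, and 1 histone gene rose. Ribosomal genes that rose numbered 8 without KO replicate 1, 2 without control replicate 1, where 2 also fell, 1 without KO replicate 3, 8 with library size only and 9 with the trend removed. Kdm5d was at adjusted p values of up to 0.102 without control replicate 1 or either remaining library. Hist1h2bp (0.0729), Rpl10 (0.0695, also lost without KO replicate 3) and Rpl3l (0.0570, also lost without control replicate 3) lost their calls without the remaining KO library.

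The third comparison asked whether the KO effect differed between RS and PS, by the interaction of genotype and cell type over all 12 libraries. Gse1, a protein of histone deacetylase complexes (chromosome 8, 120228456 to 120581390), did not pass in KO PS (log2 fold change -0.03, adjusted p = 0.958) and rose in KO RS (1.97, adjusted p = 0.00249), with a difference of 2.03 (SE 0.253, adjusted p = 0.0154). Gclc, the catalytic subunit of the first enzyme of glutathione synthesis (chromosome 9, 77754535 to 77794485), fell in KO PS (-0.66, adjusted p = 0.0391) and rose in KO RS (0.99, adjusted p = 0.00602), with a difference of 1.68 (SE 0.220, adjusted p = 0.0154). The third called gene, Cspg4, a proteoglycan of pericytes (chromosome 9, 56865033 to 56899870), lay outside the naming rule and was chosen after its values were seen. It fell in KO PS to 4, 1 and 2 counts (7 in all against 69 in controls, a ratio of 10.1 with a 95% counting interval of 4.66 to 26.1) and was at 1.06 in KO RS (adjusted p = 0.0567), with a difference of 4.34 (SE 0.651, adjusted p = 0.0487). These 3 of the 16581 genes tested were called (edgeR), while 2253 had an unadjusted p under 0.05, DESeq2 called 95 and voom 2. With the replicate block 1285 passed, with a log2 fold change of KO against control higher in RS than in PS for 1117 and lower for 168, and with the trend also removed 1870 (751 and 1119). Without replicate 1, replicate 3 or the remaining replicate edgeR called 0 genes, with 2679, 850 and 1018 at an unadjusted p under 0.05. DESeq2 called 80, 2 and 5 there, and voom 0 in each.

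Many genes called in PS were called in the same direction in RS. Of 14782 genes tested in both, 85 of the 132 that rose in PS also rose in RS, where 24.7 would be expected of independent lists (Fisher's exact test, 2-sided p = 6.56e-31). Of the 681 that fell in PS, 446 also fell in RS, where 88.2 would be expected (Fisher's exact test, 2-sided p = 2.96e-240). Among them stood Eqtn and Fhl5, which fell in both, and Stra8, Ccnb3 and Taf7l, which rose in both. The opposite directions were shared by 0 genes higher in PS and lower in RS (17.1 expected) and 3 lower in PS and higher in RS (128 expected). Across genes the Pearson correlation of both log2 fold changes was 0.656. Genes are not independent replicates, so neither it nor the Fisher p-values measure spread between samples. The 2 comparisons share no library but share replicate numbers, and spermatid RNA in PS libraries could add to the overlap. The number shared in the same direction was 531, 2592 with the replicate block (1045 higher and 1547 lower), and 10, 3 and 0 without replicate 1, replicate 3 and the remaining replicate (the last with 0 genes called in RS).

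The fourth comparison described the step from control PS to control RS. The largest rises were those of Cd74 (log2 fold change 3.95, SE 0.505, adjusted p = 1.41e-05), H2-Aa (3.55, SE 0.597, adjusted p = 0.000154) and Mgp, matrix Gla protein (3.57, SE 0.614, adjusted p = 0.000183; chromosome 6, 136872435 to 136875823), all expressed by somatic cells. The largest falls were those of Gpr55 (-5.43, SE 0.705; chromosome 1, 85938318 to 85961007) and Gpr37 (-5.25, SE 0.926; chromosome 6, 25665878 to 25690729), which encode G protein coupled receptors, and Klk1b24, one of a family of near-identical kallikrein genes (-5.42, SE 0.555; chromosome 7, 44188236 to 44192455). Their counts in control RS were 7, 6 and 14 in all, and the ratios of pooled CPM (PS over RS) were 48.1 (95% counting interval 23.1 to 121), 43.3 (19.6 to 119) and 48.5 (28.7 to 89.2). In the lists, 13 members of the protamine list and 23 acrosome genes were higher in RS (medians 2.40 and 2.04). So were 13 macrophage markers (median 2.51), while 19 Sertoli cell markers and 11 Leydig cell markers were lower (medians -2.49 and -3.78). In all, 9742 of 16581 genes differed (edgeR), 4612 higher and 5130 lower, of which 3690 and 3405 by more than 2-fold.

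The KO effect was then set against this step with somatic genes left in, whose part was not tested. Genes more than 4-fold higher in control RS than in control PS fell in KO PS as a set, with a median log2 fold change of -0.88. Of these 1224 genes, 438 fell and 13 rose (camera adjusted p = 1.07e-52, adjusted p = 0.07002 with an estimated correlation). They also fell in KO RS, with a median of -0.65 over 1641 genes, of which 598 fell and 77 rose (camera adjusted p = 4.50e-18, adjusted p = 0.173 with an estimated correlation). Genes more than 4-fold higher in control PS rose, with a median of 0.27 over 1048 genes in KO PS (17 rose and 8 fell, camera adjusted p = 3.60e-06, adjusted p = 0.276 with an estimated correlation). In KO RS the median was 0.95 over 804 genes (298 rose and 2 fell, camera adjusted p = 3.59e-16, adjusted p = 0.215 with an estimated correlation). With the block 760 fell and 28 rose in KO PS and 975 and 117 in KO RS among the genes higher in control RS, and 248 rose and 33 fell in KO PS and 474 and 3 in KO RS among those higher in control PS. The control libraries enter both sides of these comparisons. In 20 simulations of unchanged KO libraries against them the mean medians were 0.08 and -0.09 in PS and -0.08 and 0.10 in RS for the sets higher in RS and in PS. The simulated libraries were drawn independently and lack the deviations shared by a replicate number. The covariance of the KO effect with the step was -0.315 in PS against a simulated 0.0740, a difference of -0.389, and -0.468 in RS against -0.0716, a difference of -0.397. Of the genes over 8-fold higher in control RS, the 91 tested in RS had a median KO effect of 0.12 (camera adjusted p = 0.400).

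**Figure D4:**
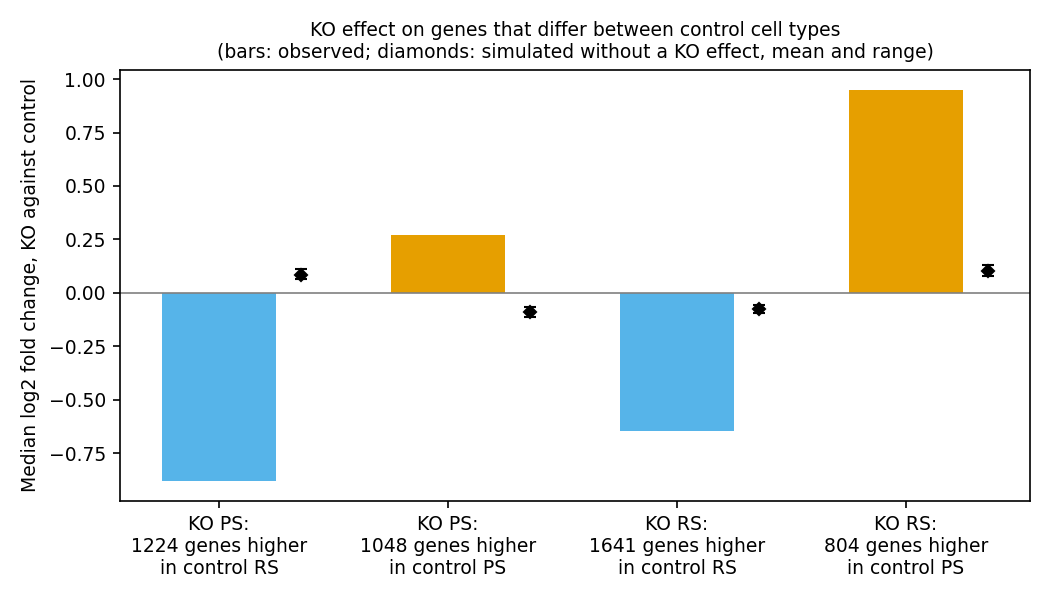
Median KO log2 fold change (vertical axis) in PS and RS of genes more than 4-fold higher in control RS or in control PS (bars), with the mean and range of 20 simulations of unchanged KO libraries (diamonds). The bars for genes higher in control RS lay at -0.88 and -0.65 and those for genes higher in control PS at 0.27 and 0.95, outside the simulated ranges.

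The authors' deposited table of the PS comparison held 1870 genes past its own rule of a fold over 1.5 and an unadjusted p under 0.01, 335 higher and 1535 lower, and that of RS 5125, 2409 higher and 2716 lower. Across genes, its log2 fold changes and those computed here had a Pearson correlation above 0.9999 in each cell type, and 793 of the 826 genes called here in PS (96.0%) and 4519 of the 4942 in RS (91.4%) had an adjusted p under 0.05 there.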

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

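The tests of fewer spermatids in KO PS libraries, of a lower share of spermatids in KO RS and of 1 library, the relabellings with the replicate block, and the removal of a trend with length and GC content, were chosen only after the results they bear on were seen.

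The KO effect differed between RS and PS for Gse1, Gclc and Cspg4, by 2.03, 1.68 and 4.34 on the log2 scale (adjusted p = 0.0154, 0.0154 and 0.0487, interaction test of edgeR). Gse1 was at -0.03 in PS and 1.97 in RS, Gclc at -0.66 and 0.99, and Cspg4 at -3.25 and 1.06. None of them was called without replicate 1, replicate 3 or the remaining replicate, where Gse1 and Gclc had adjusted p values of 0.277, 0.839 and 0.790. Under the alternatives that keep all libraries, Gse1 was at 1.66 to 2.30 and Gclc at 1.49 to 1.94, and both were called in each. Of 100 relabellings of genotype within cell types, drawn from 200, 5 gave as many genes as the real one, itself included (highest other 4241), and with the replicate block, where the interaction count was 1285, 6 gave as many (highest other 6695). Each of the other relabellings that gave as many, 4 without and 5 with the block, kept the true split of the RS libraries and so held the KO effect in RS. The 88 that did not keep it gave at most 1 gene, or 261 with the block, but hold that effect within their groups, so these counts say nothing about chance.

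By the same interaction, the KO effect on 8 gene lists differed between the cell types (camera, Benjamini-Hochberg). The lists whose KO effect was higher in RS than in PS were macrophage markers (adjusted p = 2.65e-08, median interaction of 2.14 on the log2 scale), interferon response genes (0.00189, 1.03), spermatogonial genes (0.00276, 0.95), peritubular markers (0.0189, 1.33) and p53 targets (0.0189, 0.51). Those whose KO effect was lower in RS than in PS were the acrosome (0.00276, -0.18), the flagellum (0.0189, -0.20) and post-meiotic transcription regulators (0.0189, -0.34). Each of these was lost with adjusted p = 0.721 with an estimated correlation. Without the remaining replicate the acrosome (0.149), p53 (0.149), peritubular (0.0666), post-meiotic (0.138) and flagellum (0.3004) lists were not called, and without replicate 3 the peritubular list was not (0.172). Lists gained without replicate 1 were sperm energy metabolism (0.0151), Leydig (0.00173), endothelial (0.010003) and stress genes (0.00817), and without the remaining replicate the endothelial list (0.0335). With the replicate block the list of transition proteins and protamines, whose KO effect was higher in RS than in PS, was gained (0.178 to 0.0239).

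Spermatid transcripts were lower in KO PS: 37 members of the protamine, acrosome and flagellum lists passed. A trend with length or GC content as the whole cause is argued against, since 34 of the 37 stayed lower with it removed and their median went from -1.05 to -0.94. Fewer round spermatids among KO PS could lower them too. Of 722 genes taken as hardly expressed by PS, 77.6% had a lower fold change in KO PS than in KO RS (medians -1.16 and -0.78). This share lay between the bounds set for and against this source, and picking genes in these same libraries can shift it. Of the list members, 14 of 16 in the protamine list had a lower fold change in PS than in RS, but 9 of 35 in the acrosome and 12 of 45 in the flagellum, so a change in cell share and lower transcript levels within KO PS cannot be told apart here. The genotype, which goes with Cre, stays open.

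Macrophage markers were higher in KO RS: 13 of 15 passed. A lower share of spermatids, which would raise all other cell types alike, stays open. The macrophage mean rose above the peritubular mean in all 3 pairs, by 3.86 SE of the difference (1.31), a ratio picked as the largest. Differences from the Sertoli (0.69, SE 0.649), Leydig (0.33, SE 0.879) and endothelial (0.96, SE 0.525) lists were smaller against their SE. KO replicate 3 alone is argued against because 11 of the 13 stayed higher without it. More macrophages in the KO RS libraries may account for the pattern: of 30 further macrophage genes, none in the first list or another list, 76.7% were higher and 29 had a log2 fold change over 0.5 (median 1.34). Of these 30 genes, 6 were at 10 CPM or more in control RS; the most abundant, Aif1, was lower (423 CPM in control and 247 in KO) and the next, Apoe, higher (65.5 and 139). That source stays open, with a share short of the bound set for it, as does expression of these genes by spermatids of the KO genotype, and no sort that would remove macrophages is given in the sources used here.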

How the results depend on the processing

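Removing a length and GC trend, with or without the block, was chosen after the data were seen. In PS the count of 826 genes was 1405 at an unadjusted p under 0.01 with a fold over 1.5, 1257 with DESeq2, 3476 with the replicate block, 1292 with the trend removed and 3607 with both, and 288 to 1592 with single libraries left out. In RS the count of 4942 was 8736 with the block and 8923 with block and trend removal, and 0 to 6391 with libraries left out. The interaction count of 3 was 689 at an unadjusted p under 0.01 with a fold over 1.5, 35 with library size only, 6 without a filter, 95 with DESeq2, 1285 with the block, 6 with the trend removed, 1870 with both and 0 without any 1 replicate. The overlap of 531 was 2592 with the block and 0 to 10 without 1 replicate. Hdac3 in RS was at -1.61 to -1.79 with single libraries left out, and at -1.72 (adjusted p = 0.0793) without both remaining ones. With an estimated correlation 0, 0 and 0 lists were called in PS, RS and the interaction, and with fry 0, 7 and 0. Interaction lists numbered 4 to 12 without 1 replicate. The relations to the stage step at the 4-fold limit kept their medians and lost their calls with an estimated correlation (-0.88 and 0.27 in PS, -0.65 and 0.95 in RS). At a 2-fold limit the genes higher in control RS kept theirs in KO RS (3688 genes, median -0.53, adjusted p = 0.0390 with an estimated correlation) and the other 3 sets did not (0.0618 to 0.195). Genes over 8-fold higher in control RS turned to 0.12 in KO RS (91 genes). The ribosomal list in PS had camera adjusted p values of 0.0132 to 0.938 with single libraries left out, and turned upward at 0.0235 without KO replicate 1. Fits that leave libraries out have fewer samples; for the rest the cause was not tested.

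The share of calls in PS that were higher, 16.8%, was 46.7% with the block, and trend removal moved the median of all genes in RS from 0.02 to -0.12. In the interaction, library size only moved the median of all genes from 0.11 to 0.37. List medians turned sign for ribosomal genes in PS with the trend removed (0.15), for X-linked and ribosomal genes in RS with library size only (0.11 and 0.14), and for the division (-0.10), piRNA (-0.03), corepressor (-0.11) and X-linked (0.17) lists in RS with the trend removed. No named call turned direction. Library size only ended those of Myh11, Cyp26b1, Ccnb3, Tdrd5, Kif17, Taf7l, Fasn and Hist1h4h in PS and Camk4 and Gtsf1 in RS, and trend removal those of Gopc and Gtsf1. Of 32 named calls in PS, 21 held in every alternative, and 3 of the other 11 were lost only with libraries left out. Of 60 in RS, 0 held in every alternative, because edgeR called no gene without both remaining libraries; 37 held with each single library left out and 53 in the settings that keep all libraries, and all 6 of the control comparison held. Beyond the calls and counts given with their results, the block changed no call of a named gene or of a list test. Pseudocounts on a log scale were not run, because the files hold counts. Depth limited genes near 0.172 to 0.268 CPM, the worth of 3 counts.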

Other observations

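The comparison by chromosome, the X-linked genes named here, the counts by expression level and the tests of mixed-in PS were chosen only after the results were seen, as was the removal of the trend with length and GC content.

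Of 590 X-linked genes tested, 23 rose in KO PS and 4 fell, and of 654 tested in KO RS, 219 rose and 16 fell; 21 of the 23 rose in both. The number of X-linked genes higher in KO PS was 163 with the replicate block, 3 without control replicate 1, 4 without control replicate 3, 70 without the remaining control, 4 without KO replicate 1, 10 without KO replicate 3 and 5 without the remaining KO library. It was 6 with library size only, 44 with DESeq2, 38 in 1 fit of 12 libraries and 36 with the trend removed (195 with the block as well). Without both libraries of replicate 1 or of replicate 3 edgeR called 0 higher, with 40 and 77 at an unadjusted p under 0.05, and without both remaining libraries 35. In KO RS the count of 219 was 100 without the remaining KO library, 90 without both libraries of replicate 3 and 0 without both remaining libraries (203 at an unadjusted p under 0.05). Jade3, a scaffold of histone acetyltransferase complexes (chromosome X, 20425688 to 20519939), rose in KO PS (log2 fold change 1.08, SE 0.215, adjusted p = 0.0120, edgeR) and in KO RS (1.60, SE 0.186, adjusted p = 0.00249), and kept both calls whichever 1 library was left out. Fmr1, the RNA-binding protein gene of fragile X syndrome (chromosome X, 68678541 to 68717963), rose by 1.02 in KO PS (adjusted p = 0.0306) and 1.29 in KO RS (adjusted p = 0.00313). Atrx, a chromatin remodeller (chromosome X, 105797615 to 105929403), rose by 0.89 (adjusted p = 0.0447) and 1.59 (adjusted p = 0.00304), and Suv39h1, a histone H3 methyltransferase (chromosome X, 8061171 to 8074760), by 1.10 (adjusted p = 0.0483) and 1.09 (adjusted p = 0.00628). In PS the adjusted p of Fmr1 was up to 0.134 without control replicate 1, control replicate 3, KO replicate 1 or the remaining KO library, and those of Atrx and Suv39h1 up to 0.171 and 0.192 without any library but the remaining control. Of autosomal genes in KO PS, 0.795% of 14461 were higher, against 3.90% on the X chromosome, and the medians were 0.05 and 0.47 (10.03% and 27.6% higher with the replicate block). In KO RS 33.5% of 654 X-linked genes were higher against 18.1% of 15046 autosomal genes, with medians of 0.64 and 0.00. Tested over 21 chromosomes, the X chromosome stood above the rest in PS (camera adjusted p = 1.18e-08, adjusted p = 0.695 with an estimated correlation) and in RS (0.000167, adjusted p = 0.996 with an estimated correlation), and did so by camera with each of the 12 libraries left out. The difference of the medians was 0.42 in PS and 0.63 in RS, and 0.24 to 0.62 and 0.49 to 0.77 over 19 alternatives. In the same libraries the spermatogonial, Sertoli and Leydig lists had medians of 0.38, 0.68 and 0.47 in KO PS and 1.31, 1.13 and 1.42 in KO RS, and the macrophage list -0.50 and 1.36.

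By level, 45 of the 2487 genes over 100 CPM were higher in KO RS and 655 lower, while of 5848 genes at 1 to 10 CPM 1486 were higher and 360 lower (117 and 1382, and 2224 and 758, with the block).

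In KO RS 2974 genes were higher, which pachytene cells mixed into these libraries might produce. That source is argued against for the 1064 genes (35.8%) with every KO RS library above the 9 other libraries, since mixing cannot lift a gene above its level in PS and chance gives 9.09% of genes whose KO RS libraries already lie above the control RS ones. As the source of most of the other 1910 it is argued against, since their median gene would need 96.0% of pachytene RNA and 17 would need no more than the 12.99% of the way from their control RS to their control PS level gained by the median of all 165 genes over 8-fold higher in control PS (median KO effect 1.34, 66 rose), while 4 such meiotic transcripts (Fbxo43, Piwil1, Tdrd1 and Tdrd5) stood at 1.19%, 4.16%, 8.42% and 9.23% of that way and the 9 at least 4-fold higher at up to 40.2%. A trend with length or GC content as the whole cause is argued against, since 79.7% of the genes stayed higher with it removed and their median went from 1.25 to 1.03. Mixing by a smaller share, RNA of other cell types, not tested for these genes as a set, and the genotype stay open. The 165 can include somatic genes and cannot tell these apart.

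Other splits were counted for each comparison. For genes changed in PS, in RS and between controls, 1 of 10 splits, the real one, gave as many (826, 4942 and 9742), and the highest other gave 0. Each other split holds the real difference within its groups, so these gene counts say nothing about chance. For the lists, 4 of 10 splits gave as many as the 11 in PS (highest other 14), and 5 of 10 as many as the 13 in RS (highest other 16). With 10 splits the share cannot fall under 0.05. Of the 4 splits that part all 3 pairs, all but the real one gave 0 genes, 4 to 8 lists in PS and 7, 13 and 15 in RS. Splits that part 1 pair also gave 0 genes. For the overlap of 531 genes, 1 of 100 relabellings, the real one, gave as many and the highest other gave 0. No other split called a gene, so no other relabelling had calls to share, and this count says nothing about chance.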
